A study of Mus musculus with 12 samples.

How the data were processed

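RNA was measured in 12 placenta libraries of mice labelled IL-10 -/-, in 4 groups of 3. Per the labels, RNA was isolated with a column kit, messenger RNA was selected with oligo-dT, libraries were stranded by dUTP incorporation, and sequencing was done on the DNBSEQ platform. The deposited files hold, per the file headers, a read count and an FPKM value (fragments per kilobase of transcript, scaled to library size) for each of 18178 genes in each library. The deposited read counts are expected counts, estimated per gene before deposit by the authors and not normalised between samples. This was read from the values, of which 7.99% are not whole numbers and whose library totals differ. FPKM values deposited by the authors are scaled to library size and transcript length. The submitters' processing notes name Bowtie2 2.2.5, RSEM 1.2.8, DESeq2 and the mouse build GRCm38.p6, without saying which tool did which step. The annotation and the strand setting of the counting are not given in the sources used here. The 8 columns of group means in the files were not used. The labels do not say whether the 3 libraries of a group come from separate animals or litters, so every p-value measures spread between these samples and no wider population.

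Counts were rounded to whole numbers and tested with edgeR 4.0.16 under R 4.3.3. TMM scaling was used, genes of low count were removed with filterByExpr by group, and 14669 genes were left. A quasi-likelihood F test was fitted to all 12 libraries with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05 and no fold threshold. All tests were two-sided. The common biological coefficient of variation was 0.316. Levels are given as CPM, counts scaled to a common library size with the TMM factors, as mean ± SD over 3 libraries, and changes as log2 fold changes with the standard error (SE) or the 95% confidence interval of the fit. Gene IDs were looked up in the GRCm38.p6 gene table, where 18067 of 18178 (99.4%) matched, and positions are those of that table.

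The 4 main comparisons were PE serum against NP serum, each disaccharide with PE serum against PE serum alone, and trehalose against lactotrehalose. The 2 secondary comparisons set each disaccharide group against NP serum. The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except where an alternative or a test is said to have been chosen later. Under that rule, a comparison in which fewer than 10 genes passed names the 10 genes of lowest p with a mean log2 CPM of at least 1 as values. It also names up to 4 members of lowest p from each list past its test and, whatever the test, from the autophagy, lysosome, endoplasmic reticulum (ER) stress, amyloid and preeclampsia lists. It adds a fixed set, namely Il10, Tfeb, Lamp1, Sqstm1, Map1lc3b, Flt1, Eng, Pgf, Ttr, App, Treh and Slc2a8. Members are not all printed, and a gene named outside the rule is said to be so.

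For pathways and for cell types of the placenta and its neighbouring tissues, 39 gene lists were written, and the 35 with at least 5 tested members were tested. The lists of mitochondrially encoded, X inactivation, Y-linked and B cell genes had fewer tested members and were not tested as lists. The main test was camera (limma 3.58.1) on log2 CPM with an inter-gene correlation preset to 0.01, adjusted over the lists of a comparison. Camera asks whether a list's members moved more one way than other genes did. The same test with a correlation estimated for each list, and fry, which asks whether a list's genes moved one way on balance without comparing them with other genes, stand beside it. A list's score in a library is the mean log2 CPM of its tested members relative to their mean over the 12 libraries.

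Alternatives were RLE and total-count scaling, no filter, a filter of at least 20 counts in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1 and on log2(FPKM + 1) without a filter, only the 2 groups compared, the replicate number as a block, robust dispersion estimation, and each library left out in turn. Each changed 1 choice, except that those on FPKM changed the unit, the test and the filter together and that DESeq2 also scales and filters in its own way. Another 5 alternatives were chosen after seeing the data, namely yolk sac and smooth muscle scores as covariates, a Y-linked score as a covariate, a correction for transcript length, the fit without the 3 libraries lowest in yolk sac markers, and the fit without the 2 most alike libraries of different groups.

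The tests were also tested on simulated data with the gene levels, library sizes and spread of the fit to all 12 libraries. In these, 100 genes were changed at each fold in the trehalose libraries, and trehalose was tested against PE serum. Of genes changed by 2-fold, edgeR recovered 15% and DESeq2 41%; of genes changed by 4-fold, edgeR recovered 83% and DESeq2 96%. False calls numbered 3 with edgeR, 49 with DESeq2, 2 with limma-voom and 4 with limma on FPKM. In 5 simulated sets without any effect, 0 lists passed camera, but genes were simulated independently, so this does not show how often camera calls lists whose members vary together. Other splits of the real trehalose and PE serum libraries gave 5 to 14 lists. In a simulated set whose lysosome list was raised by 1.5-fold, that list passed with a simulated adjusted p of 8.34e-27 by camera, 3.73e-05 with an estimated correlation and 1.18e-05 by fry. Genes were independent there too, so this does not show how well these tests find a list whose members vary together, or a smaller change. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.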

Results

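Gene expression was measured by RNA sequencing in placenta collected at gestational day 17 from mice labelled IL-10 -/-, the name for a deletion of the gene of the anti-inflammatory cytokine interleukin 10. The 12 libraries form 4 groups of 3: exposure to serum from normal human pregnancy (NP serum), to human preeclampsia serum (PE serum), to PE serum with trehalose, and to PE serum with lactotrehalose. Preeclampsia is a hypertensive disorder of pregnancy. Trehalose is a disaccharide made of glucose that is used to induce autophagy, and lactotrehalose is an analog in which a glucose unit is replaced by galactose. Vehicle or a disaccharide at 2 g/kg was injected intraperitoneally on gestational days 9, 11 and 14. The series title names autophagy, proteinopathy and preeclampsia, so the comparisons ask what PE serum does to the placental transcriptome and whether either disaccharide alters it.

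Total counts were 16630971, 18030639 and 18094191 for NP serum 1 to 3, and 18082429, 17962993 and 18105703 for PE serum 1 to 3. They were 17837904, 18192863 and 17773746 for trehalose 1 to 3, and 17668369, 17572051 and 15593035 for lactotrehalose 1 to 3. The 10 most abundant genes took from 9.82% (lactotrehalose 3) to 19.3% (trehalose 2) of a library's counts. Il10 (gene ID 16153, chromosome 1, 131019845 to 131024970) had 22 to 65 counts in each library. Its level was 2.24 ± 0.213 CPM with NP serum, 1.80 ± 0.647 with PE serum, 2.04 ± 0.21 with trehalose and 2.72 ± 1.34 with lactotrehalose (mean ± SD, n = 3, as for all levels). A count over the whole gene does not show whether the reads cover the deleted part.

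Libraries of the same group differed in markers of tissues that lie beside the placenta. The yolk sac endoderm list (23 tested members, score in log2 units) was at -3.34 in trehalose 2, -3.38 in trehalose 3 and -3.06 in lactotrehalose 3, against 1.04 in trehalose 1, 0.74 in lactotrehalose 2, -0.84 in lactotrehalose 1 and 0.44 to 2.08 in the NP and PE serum libraries. Afp, alpha-fetoprotein, was at 119, 106 and 212 CPM in those 3 low libraries and at 1380 to 26900 CPM in the other 9. The uterine smooth muscle list was highest in lactotrehalose 3 (2.29), NP serum 3 (1.74), trehalose 2 (1.09) and NP serum 1 (0.82), and lay between -1.19 and -0.13 in the other 8. Actg2, a smooth muscle actin, was at 513 CPM in lactotrehalose 3 and 347 CPM in NP serum 3. Afp and Actg2 were chosen after their values were seen.

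**Figure D1:**
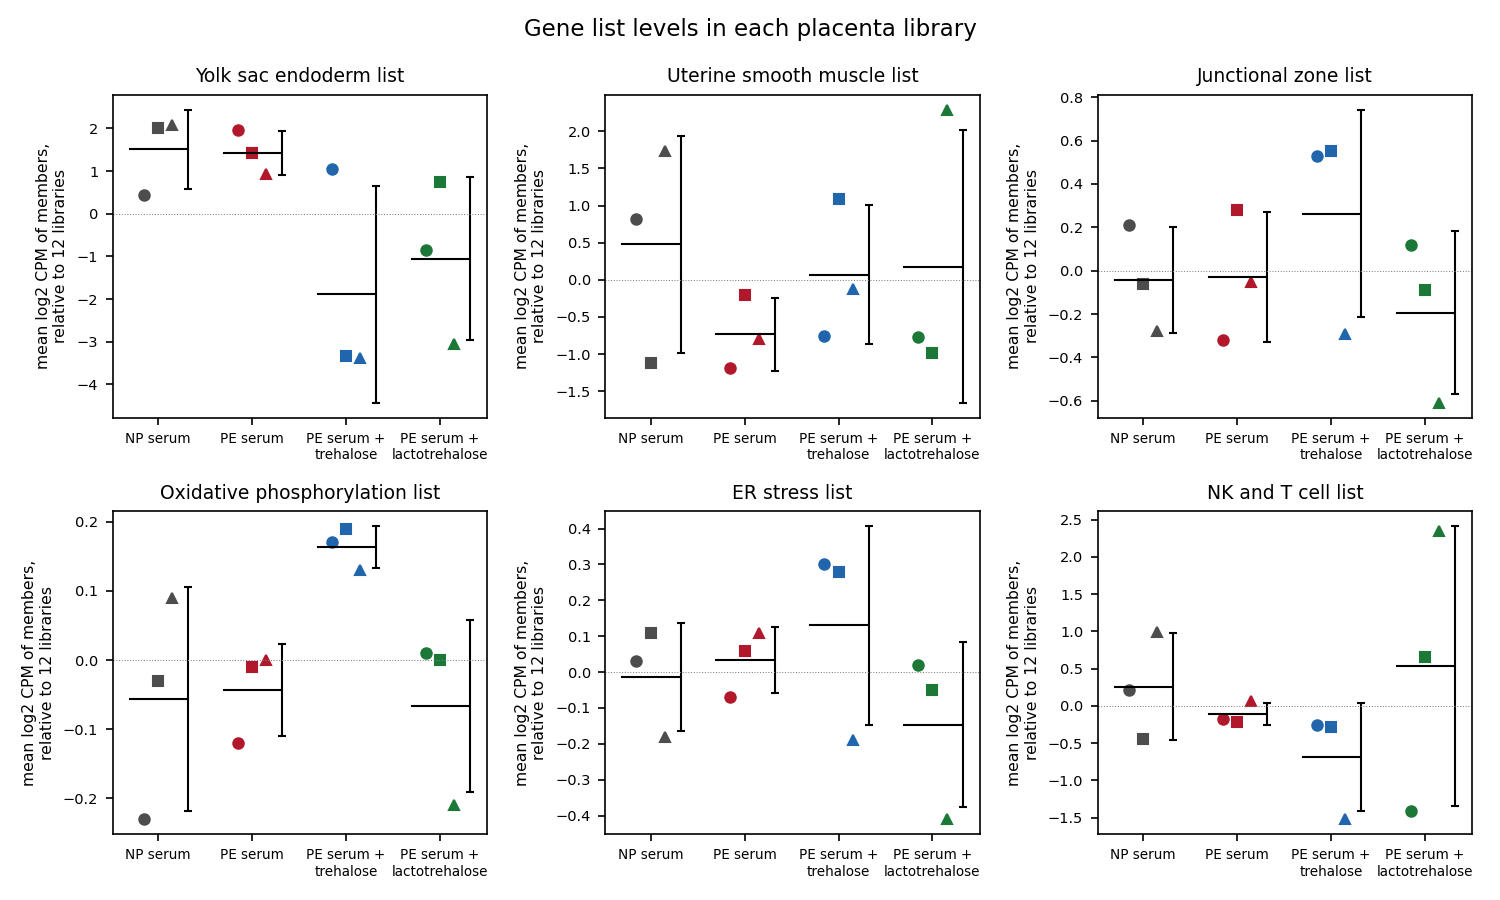
Score of 6 gene lists in each of the 12 libraries (y axis: mean log2 CPM of the list's tested members relative to the mean of the 12 libraries; x axis: the 4 groups). Points are libraries (circle, square and triangle for replicates 1, 2 and 3), the line is the group mean and the bar its SD; the yolk sac panel shows trehalose 2 and 3 and lactotrehalose 3 between -3.38 and -3.06, apart from the other 9 libraries.

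PE serum was compared with NP serum to ask what the preeclampsia serum changed. Collagen and other matrix genes were lower as a list, with 27 of 29 members lower and a median log2 fold change of -0.48 (adjusted p = 3.59e-06 by camera). Uterine smooth muscle genes were lower in 14 of 14 members (median -1.43, adjusted p = 0.000294), and fetal mesenchyme and pericyte genes in 13 of 15 (median -0.64, adjusted p = 0.00423). Cytosolic ribosomal protein genes were higher in 41 of 48 members, by a small median of 0.25 (adjusted p = 3.5e-07). With an estimated correlation each of these 4 calls was lost (adjusted p = 0.876), and by fry the smallest adjusted p was 0.98. In each of the 4 lists all 3 PE serum libraries lay on the tested side of the NP serum mean, and none of the 4 separated the groups fully. The smooth muscle and mesenchyme calls ended without NP serum 3, the library of that group highest in smooth muscle markers (median -0.83, adjusted p = 0.146, and median -0.50, adjusted p = 0.0696). With the yolk sac and smooth muscle scores as covariates the matrix and mesenchyme calls ended (medians -0.27 and -0.24, adjusted p = 0.0735 and 0.171). The smooth muscle list is its own covariate there, so that fit does not test it. The ribosomal median was 0.12 without NP serum 1 and 0.11 without PE serum 2. The number of lists past the threshold was 4 with all libraries, 15 without NP serum 1 and 10 without PE serum 1.

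Among matrix genes, Col1a1, a chain of type I collagen (gene ID 12842, chromosome 11, 94936224 to 94953042), was at 134 ± 90.8 CPM with PE serum and 985 ± 1210 CPM with NP serum (log2 fold change -2.88, SE 1.29). Elastin (Eln) was at 35.2 ± 17.6 against 177 ± 189 CPM, and fibrillin (Fbn1) at 31.1 ± 6.18 against 67.9 ± 44.5 CPM. Col1a1 and Col1a2 are members of both the matrix and the mesenchyme list. Myh11, the smooth muscle myosin heavy chain, had a log2 fold change of -2.20 (SE 1.17), and Acta2, smooth muscle actin, of -1.58 (SE 0.83). The ribosomal members of lowest p, Rps5, Rps15, Rpl19 and Rpl13, had log2 fold changes of 0.40 to 0.50. No member of these lists passed the test, either over all genes or adjusted over the list alone.

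The lists nearest to the study's title did not pass with PE serum. Autophagy genes had a median log2 fold change of 0.08 (28 of 40 members higher, adjusted p = 0.126), and Calcoco1, Atg14, Map1lc3a and Gabarap, its members of lowest p, had unadjusted p-values of 0.156 to 0.243. Lysosome genes had a median of -0.09 (adjusted p = 0.126), amyloid and proteinopathy genes of -0.10 (adjusted p = 0.554), ER stress genes of 0.07 (adjusted p = 0.695), and preeclampsia and angiogenic genes of -0.03 (adjusted p = 0.857), with scores of 0.05 to 0.07 against 0.08 to 0.13 that did not overlap (exact permutation p = 0.1). The lysosomal protease cathepsin B (Ctsb) was at 1970 ± 24.3 against 3440 ± 1420 CPM, and Tpp1, a lysosomal peptidase, at 164 ± 29.6 against 264 ± 79 CPM, lower in all 3 PE serum libraries than in any NP serum library. Aplp1, a homolog of the amyloid precursor, had a log2 fold change of -0.67 (SE 0.29). Flt1 (gene ID 14254, chromosome 5, 147561604 to 147726438), whose soluble form is raised in human preeclampsia, was at 1470 ± 307 against 1450 ± 220 CPM (log2 fold change 0.01, 95% interval -0.81 to 0.83). The gene-level count does not separate soluble from full-length Flt1. Endoglin (Eng) had a log2 fold change of -0.49 (SE 0.32) and Pgf, placental growth factor, of 0.14 (SE 0.30). None of these genes passed the test.

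No single gene passed edgeR's threshold for PE against NP serum, and DESeq2 and limma-voom also called 0. At an unadjusted p under 0.05 there were 251 genes, 58 higher and 193 lower, where chance gives 733 of 14669. The 3 PE serum libraries did not overlap the 3 NP serum libraries in 981 genes (6.69%, where chance gives 10%). Of the genes of lowest p, Ccnd1, a D-type cyclin, was at 10.4 ± 2.72 against 18.7 ± 5.27 CPM, and Nos1ap, an adaptor of neuronal nitric oxide synthase, at 10.5 ± 1.56 against 5.06 ± 1.62 CPM. Susd2 was at 20.6 ± 0.207 against 55.5 ± 31.7 CPM and Ehd3 at 19.4 ± 2.11 against 29.7 ± 3.84 CPM. Their adjusted p was 0.966.

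Trehalose with PE serum was compared with PE serum alone to ask what trehalose changed. Yolk sac endoderm genes were lower in 22 of 23 members (median -1.91, adjusted p = 5.28e-12). Sterol synthesis genes were lower in 21 of 24 (median -0.79, adjusted p = 0.000115), complement and coagulation genes in 21 of 35 (median -0.45, adjusted p = 0.00234) and decidual stroma genes in 20 of 22 (median -0.46, adjusted p = 0.00774). Oxidative phosphorylation genes were higher in 32 of 36 members (median 0.21, adjusted p = 5.09e-05), junctional zone trophoblast genes in 25 of 28 (median 0.37, adjusted p = 0.00392) and fetal erythroid genes in 16 of 16 (median 0.53, adjusted p = 0.00392). Proteasome genes (22 of 33 higher, median 0.10, adjusted p = 0.03) and chaperone genes (21 of 28 higher, median 0.17, adjusted p = 0.0474) also passed. With an estimated correlation the 9 calls were lost (adjusted p = 0.756), and by fry the smallest adjusted p was 0.41. All 3 trehalose libraries lay on the tested side of the PE serum mean in 7 of these lists, and 2 of 3 did so for the junctional zone and the chaperones. The oxidative phosphorylation, proteasome, complement and decidual scores did not overlap between the groups (exact permutation p = 0.1, the smallest that 3 against 3 allows), and neither did those of 6 lists that did not pass, among them autophagy, amyloid and preeclampsia genes.

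The low yolk sac score was a feature of trehalose 2 and 3, while trehalose 1 (1.04) lay within the PE serum range of 0.92 to 1.95. Without those 2 libraries and lactotrehalose 3, the sterol list had a median of -0.20 (adjusted p = 0.902), the complement list of -0.34 (adjusted p = 0.129) the decidual list of -0.38 (adjusted p = 0.0627) and the chaperone list of 0.08 (adjusted p = 0.0729). The oxidative phosphorylation list then had a median of 0.17 (adjusted p = 3.84e-05), the junctional zone list of 0.58 (adjusted p = 5.91e-11) and the erythroid list of 0.53 (adjusted p = 0.00109). With the yolk sac and smooth muscle scores as covariates the sterol median was 0.08 (adjusted p = 0.195), the complement median -0.11 (adjusted p = 0.619) and the decidual median -0.19 (adjusted p = 0.286), and the chaperone call ended (median 0.12, adjusted p = 0.199). The oxidative phosphorylation, junctional zone and proteasome medians were then larger, at 0.32, 0.56 and 0.20 (adjusted p = 2.04e-08, 8.67e-06 and 0.00201). The fit without 3 libraries leaves trehalose 1 as the only library of its group, assumed to vary like the other groups, and does not test the yolk sac list, by which the libraries were chosen. Without trehalose 1 the yolk sac median was -5.05 and the sterol median -1.33, and without PE serum 1 the sterol median was -0.44.

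Several trehalose calls ended when a single library was left out, some with medians about as large as before. The erythroid call ended without PE serum 1 (median 0.32, adjusted p = 0.283), and the median was 0.32 without trehalose 3 as well. The junctional zone call ended without PE serum 1, trehalose 1 or trehalose 2 (medians 0.25, 0.28 and 0.20, adjusted p = 0.151, 0.201 and 0.0977), and its median was 0.61 without PE serum 2 and 0.60 without trehalose 3. The decidual call ended without trehalose 3 (median -0.19, adjusted p = 0.28), and its median was -0.80 without trehalose 2. The proteasome call ended without PE serum 1, PE serum 2, trehalose 1 or trehalose 2 (medians 0.06, 0.11, 0.12 and 0.09, adjusted p = 0.0819, 0.0852, 0.117 and 0.0585), and the chaperone call without PE serum 2, PE serum 3, trehalose 1 or trehalose 2 (medians 0.13, 0.15, 0.21 and 0.11, adjusted p = 0.178, 0.0865, 0.113 and 0.215). The chaperone call also ended with the replicate block, without the low-count filter and with only the 2 groups in the fit, where the medians were 0.17, 0.17 and 0.19 (adjusted p = 0.057, 0.0504 and 0.0633). The erythroid median was 0.20 without the filter (adjusted p = 0.0379). The complement median was -0.27 without PE serum 1, -0.70 without trehalose 2 and -0.29 without trehalose 3. Short transcripts were higher with trehalose than long ones, with medians of 0.14 up to 1645 bp and -0.19 from 3986 bp. After a correction for transcript length the adjusted p was 0.0602 for oxidative phosphorylation (median 0.09), 0.0602 for the junctional zone (median 0.25), 0.883 for the proteasome (median 0.01) and 0.178 for the chaperones (median 0.09). With total-count scaling the proteasome (median 0.03) and the chaperones (median 0.10) both had an adjusted p of 0.106.

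Of the yolk sac genes, fibrinogen beta chain (Fgb) was at 45.8 ± 75.2 CPM with trehalose and 497 ± 413 CPM with PE serum, and the tight junction gene Cldn2 at 30.1 ± 19.4 against 108 ± 84.2 CPM. Of the sterol genes, Fdps, farnesyl diphosphate synthase, was at 21.6 ± 10.5 against 50.6 ± 14.3 CPM. Igfbp1, a decidual product, was at 7.25 ± 5.32 against 25 ± 7.97 CPM, and the complement gene C2 at 22.7 ± 12.9 against 67.6 ± 33.3 CPM. Ndufv2, a subunit of respiratory complex I, was at 70.6 ± 0.631 against 54.3 ± 4.51 CPM, and Atp5g1, a subunit of ATP synthase, at 72.2 ± 3.11 against 45.4 ± 9.14 CPM. The prolactin-family genes Prl2c3, Prl2c2, Prl6a1 and Prl7d1 of the junctional zone had log2 fold changes of 0.51 to 0.67. The proteasome assembly factor Pomp had a log2 fold change of 0.53 (SE 0.14). Hspe1, a mitochondrial co-chaperonin, was at 63.4 ± 5.68 against 39.9 ± 1.74 CPM and was the only member of these lists to pass adjusted over the list alone (adjusted p = 0.0351). None passed over all genes with edgeR.

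Autophagy and lysosome genes did not pass as lists with trehalose. The autophagy median was -0.07 (15 of 40 members higher, adjusted p = 0.37), with scores of -0.06 to 0.01 with trehalose and 0.03 to 0.14 with PE serum, and the members of lowest p included Tax1bp1 (log2 fold change -0.59, SE 0.28) and Rb1cc1 (-0.73, SE 0.35). The lysosome median was 0.06 while the mean was -0.04 (25 of 45 higher, adjusted p = 0.584). Within it the protease cathepsin H (Ctsh) was at 62.9 ± 20.8 against 144 ± 56.4 CPM, and prosaposin (Psap) at 2310 ± 332 against 1630 ± 118 CPM. Tfeb, the transcription factor of lysosomal genes (gene ID 21425, chromosome 17, 47737037 to 47792416), had a log2 fold change of 0.27 (95% interval -0.28 to 0.82). Those of Lamp1 (gene ID 16783, chromosome 8, 13159161 to 13175338), Sqstm1 and Map1lc3b were -0.18 (interval -0.53 to 0.16), 0.04 (-0.30 to 0.37) and -0.07 (-0.40 to 0.27). The amyloid list had a median of -0.04 and a mean of -0.22 (adjusted p = 0.806), with scores of -0.26 to 0.02 against 0.05 to 0.19, and Apoe, a lipid carrier, was at 187 ± 36.1 against 472 ± 144 CPM. ER stress genes had a median of 0.11 (adjusted p = 0.125), with the ER chaperone calreticulin (Calr) at 3670 ± 755 against 1960 ± 451 CPM. Preeclampsia genes had a median of -0.01 and a mean of -0.12 (adjusted p = 0.478), with scores of -0.31 to 0.04 against 0.05 to 0.07, and Flt1 had a log2 fold change of 0.12 (interval -0.70 to 0.94). The autophagy, amyloid and preeclampsia scores thus lay lower without overlap (exact permutation p = 0.1 for each), although the lists did not pass. In trehalose 1 to 3 the amyloid scores were 0.02, -0.26 and -0.25 and the preeclampsia scores 0.04, -0.20 and -0.31. The yolk sac scores there were 1.04, -3.34 and -3.38, so most of both falls lay in the 2 libraries low in yolk sac markers. Ttr, transthyretin (gene ID 22139, chromosome 18, 20664209 to 20674326), which is also a yolk sac gene, was at 393, 13.2 and 10.9 CPM in trehalose 1 to 3 and at 391 to 414 CPM in PE serum libraries.

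At single genes, trehalose against PE serum gave 0 calls with edgeR and limma-voom and 26 with DESeq2, 16 higher and 10 lower. At an unadjusted p under 0.05 edgeR had 1283 genes, 583 higher and 700 lower, where chance gives 733, and 3581 genes (24.4%) did not overlap, where chance gives 10%. These chance values are averages, and where genes vary together a count can lie far above or below them. For PE against NP serum the values were 251 genes and 6.69%, both below. The excess is thus no test of an effect of trehalose, and trehalose 2 and 3 were both low in yolk sac markers. The gene of lowest p was Irs2, an insulin receptor substrate (gene ID 384783, chromosome 8, 10984681 to 11008929), at 20.5 ± 8.15 against 64.1 ± 9.84 CPM (log2 fold change -1.65, 95% interval -2.34 to -0.95). Glmp, a lysosomal membrane glycoprotein (gene ID 56700, chromosome 3, 88325023 to 88328631), was at 429 ± 61.6 against 244 ± 20 CPM (log2 fold change 0.81, interval 0.45 to 1.18). Glmp is not a member of the lysosome list used. Rbx1, a component of cullin ubiquitin ligases, was at 48.6 ± 4.16 against 30.1 ± 2.71 CPM, Tmem14c at 90.7 ± 2.27 against 59.5 ± 1.76 CPM, and Nos1ap at 3.54 ± 0.33 against 10.5 ± 1.56 CPM. In each of these 5 genes the 3 libraries of the groups did not overlap, the edgeR adjusted p was 0.555 and DESeq2 called the gene.

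**Figure D2:**
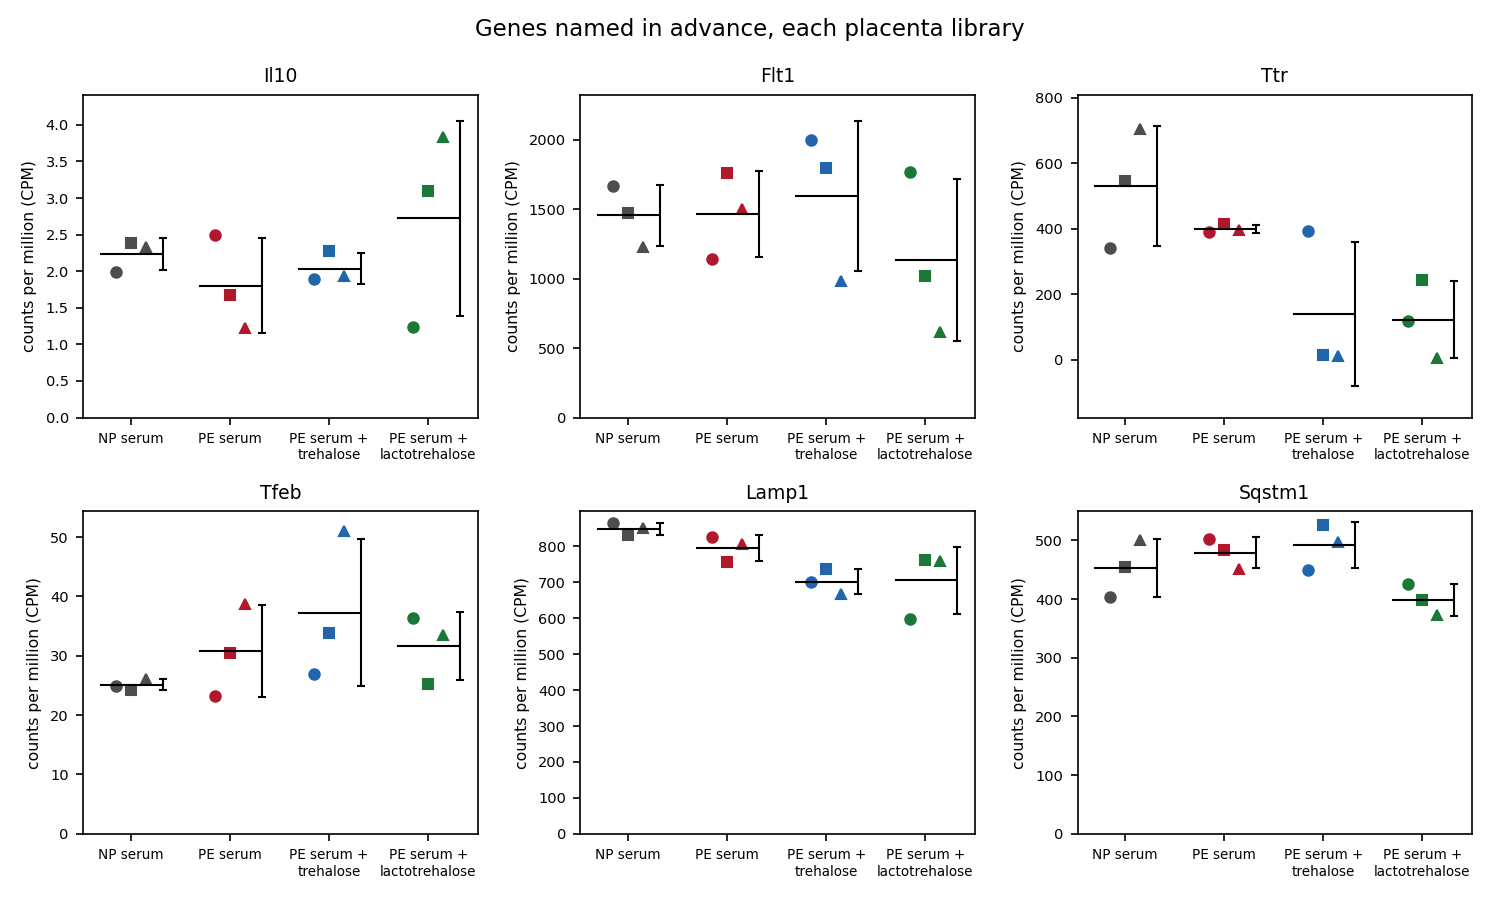
Level of Il10, Flt1, Ttr, Tfeb, Lamp1 and Sqstm1 in each library (y axis: TMM-scaled CPM; x axis: the 4 groups). Points are libraries (circle, square and triangle for replicates 1, 2 and 3), the line is the group mean and the bar its SD; Ttr was at 13.2, 10.9 and 6.55 CPM in trehalose 2, trehalose 3 and lactotrehalose 3, and none of the 6 genes passed the test in any comparison.

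Lactotrehalose with PE serum was compared with PE serum alone for the same question. Yolk sac endoderm genes were lower in 23 of 23 members (median -1.87, adjusted p = 2.96e-11) and sterol synthesis genes in 22 of 24 (median -0.82, adjusted p = 1.67e-08). Ribosomal protein genes were lower in 40 of 48 (median -0.24, adjusted p = 0.000472). Endothelial genes were higher in 16 of 18 members (median 0.28, adjusted p = 0.00238), labyrinth and syncytiotrophoblast genes in 14 of 17 (median 0.24, adjusted p = 0.0372), smooth muscle genes in 13 of 14 (median 1.37, adjusted p = 0.00745) and mesenchyme and pericyte genes in 12 of 15 (median 0.65, adjusted p = 0.0407). With an estimated correlation the 7 calls were lost (adjusted p = 0.835), and by fry the smallest adjusted p was 0.85. All 3 lactotrehalose libraries lay on the tested side of the PE serum mean in 5 of these lists, and 1 of 3 did so for smooth muscle and mesenchyme. Without lactotrehalose 3 the smooth muscle median turned to -0.26 (adjusted p = 0.797), the mesenchyme median was 0.08 (adjusted p = 0.81), the endothelial median 0.14 and the ribosomal median -0.15. Without PE serum 1 the smooth muscle, mesenchyme and labyrinth calls ended with medians of 1.26, 0.68 and 0.26 (adjusted p = 0.0914, 0.0619 and 0.0898), and the sterol median was -0.43. The ribosomal call ended without PE serum 2 (median -0.12, adjusted p = 0.196) or lactotrehalose 2 (median -0.25, adjusted p = 0.0739), and the labyrinth call without PE serum 2, lactotrehalose 1 or lactotrehalose 2 (medians 0.29, 0.28 and 0.36, adjusted p = 0.105, 0.11 and 0.0739). Without lactotrehalose 2 the medians were -3.21 for the yolk sac, 0.43 for the endothelium and 1 for the mesenchyme, and the endothelial median was 0.46 without PE serum 3. The mesenchyme call also ended with RLE scaling, total-count scaling and the length correction, although the medians were 0.68, 0.71 and 0.77 (adjusted p = 0.0509, 0.0614 and 0.0518). With the yolk sac and smooth muscle scores as covariates 0 lists passed, which for the yolk sac and smooth muscle lists is no test, since their own scores were the covariates. The endothelial, labyrinth, mesenchyme and ribosomal medians were then -0.01, 0.06, 0.06 and -0.09 (adjusted p = 0.797, 0.797, 0.979 and 0.211 by camera).

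Without the 3 libraries lowest in yolk sac markers, the sterol list had a median of -0.61 with lactotrehalose. That fit does not remove the yolk sac difference. The yolk sac scores left were -0.84 in lactotrehalose 1 and 0.74 in lactotrehalose 2, against 0.92 to 1.95 with PE serum. With all libraries the sterol call was lost with an estimated correlation (adjusted p = 0.835), and with the yolk sac and smooth muscle covariates the sterol median was -0.11 (adjusted p = 0.534). Fgb was at 52.3 ± 63.8 against 497 ± 413 CPM and Fdps at 23.9 ± 10.4 against 50.6 ± 14.3 CPM. Of the labyrinth genes, Synb, the fusion protein syncytin B, was at 336 ± 163 against 124 ± 21.9 CPM, while the epithelial gene Epcam was at 46.5 ± 7.24 against 75 ± 23.9 CPM. The endothelial adhesion gene Esam was at 209 ± 47.5 against 141 ± 14.7 CPM. Myh11 was at 209 ± 296 against 38.9 ± 18.7 CPM. Of the ribosomal genes, Rps18, Rps5 and Rpl19 had log2 fold changes of -0.46, -0.50 and -0.45, and Rps6 of 0.58. None of these members passed, over all genes or adjusted over the list alone.

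Autophagy genes were lower in 29 of 40 members with lactotrehalose, without passing (median -0.12, adjusted p = 0.0691). Sqstm1, an autophagy receptor, was at 399 ± 27 against 480 ± 25.7 CPM, with all 3 lactotrehalose libraries below the PE serum libraries (log2 fold change -0.27, 95% interval -0.60 to 0.07). Tfeb had a log2 fold change of 0.04 (interval -0.51 to 0.59), Lamp1 of -0.17 (-0.52 to 0.17) and Map1lc3b of -0.12 (-0.46 to 0.22). Lysosome genes had a median of -0.08 (adjusted p = 0.214), and Ctsh was at 61.8 ± 23.4 against 144 ± 56.4 CPM. The amyloid list had a median of 0.02 and a mean of -0.13 (adjusted p = 0.698), and Apoe was at 207 ± 50.1 against 472 ± 144 CPM. ER stress genes were lower in 21 of 26 members (median -0.15, adjusted p = 0.0637), with Herpud1, a factor of ER-associated degradation, at 87.3 ± 21.3 against 129 ± 9.19 CPM. The preeclampsia list had a median of 0.08 (adjusted p = 0.698), and Flt1 a log2 fold change of -0.37 (interval -1.19 to 0.45). Ttr was at 118, 243 and 6.55 CPM in lactotrehalose 1 to 3.

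At single genes, lactotrehalose against PE serum gave 0 calls with edgeR and limma-voom and 1 with DESeq2. At an unadjusted p under 0.05 edgeR had 581 genes, 255 higher and 326 lower, where chance gives 733, and 1574 genes (10.7%) did not overlap. The gene DESeq2 called, also the one of lowest p with edgeR, was Plekhg6, a guanine nucleotide exchange factor (gene ID 213522, chromosome 6, 125362651 to 125381615). It was at 11 ± 0.606 CPM with lactotrehalose and 20.5 ± 0.355 CPM with PE serum (log2 fold change -0.90, 95% interval -1.22 to -0.57, adjusted p = 0.893 with edgeR and 5e-04 with DESeq2). Foxa2, a transcription factor of endoderm, was at 4.88 ± 0.737 against 15.2 ± 7.39 CPM, the chemokine gene Cxcl16 at 8.89 ± 1.1 against 18.3 ± 4.52 CPM, and Slc1a5, an amino acid transporter, at 87.1 ± 16.3 against 51.8 ± 6.19 CPM.

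Trehalose and lactotrehalose, given at the same dose on the same days, were compared directly to ask whether the change of glucose to galactose altered the response. Oxidative phosphorylation genes were higher with trehalose in 33 of 36 members (median 0.23, adjusted p = 2.41e-08), and the scores of the groups did not overlap (exact permutation p = 0.1). Junctional zone trophoblast genes were higher in 26 of 28 (median 0.54, adjusted p = 1.03e-07), ER stress genes in 23 of 26 (median 0.29, adjusted p = 2.24e-06) and ribosomal protein genes in 42 of 48 (median 0.18, adjusted p = 5.64e-05). Proteasome genes (25 of 33 higher, median 0.11, adjusted p = 0.0078) and lysosome genes (29 of 45 higher, median 0.10, adjusted p = 0.0299) passed with smaller medians. Natural killer and T cell genes were lower in 9 of 10 (median -2.46, adjusted p = 0.00776) and decidual stroma genes in 19 of 22 (median -0.60, adjusted p = 0.00569). The yolk sac list passed as lower (adjusted p = 0.0387), with scores of -1.89 with trehalose and -1.05 with lactotrehalose, although the median of its fitted fold changes was 0.06 and their mean -0.04. With an estimated correlation the 9 calls were lost (smallest adjusted p = 0.565), and by fry the smallest was 0.69. The trehalose libraries on the tested side of the lactotrehalose mean were 2 of 3 for the junctional zone, ER stress, lysosome and yolk sac lists and 3 of 3 for the other 5. Without lactotrehalose 3, which had the highest smooth muscle and killer cell scores, the killer cell median was -1.10 (adjusted p = 0.772), the decidual median -0.32 (adjusted p = 0.381), the junctional zone median 0.28 (adjusted p = 0.00966), the ER stress median 0.19 (adjusted p = 0.0372) and the yolk sac median -0.46 (adjusted p = 1.48e-06).

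Some of these calls between the disaccharides also ended without other single libraries. The killer cell call ended without trehalose 3 (median -2.05, adjusted p = 0.182), and without the low-count filter (adjusted p = 0.109, median -1.11). The decidual call ended without trehalose 3 (median -0.42, adjusted p = 0.492) or lactotrehalose 2 (median -0.31, adjusted p = 0.0958). The lysosome call ended without trehalose 1, trehalose 2 or lactotrehalose 1 (medians 0.04, 0.06 and 0.06, adjusted p = 0.196, 0.222 and 0.45), and its median was 0.16 without trehalose 3 and 0.17 without lactotrehalose 2. The proteasome call ended without lactotrehalose 1 (median 0.07, adjusted p = 0.242) or lactotrehalose 3 (median 0.10, adjusted p = 0.0508). The yolk sac median went from -3.54 without trehalose 1 to 1.45 without lactotrehalose 2, and was 0.51 without trehalose 2, 0.50 without trehalose 3 and -0.18 without lactotrehalose 1, with its call ending in the last 4 of these (adjusted p = 0.831, 0.966, 0.981 and 0.27). The junctional zone median was 0.83 without lactotrehalose 1 and 0.33 without trehalose 2, and the ribosomal median 0.29 without lactotrehalose 1. With total-count scaling the median of all genes was -0.13 in place of -0.02, a shift of -0.11. The oxidative phosphorylation, ribosomal and ER stress medians were then 0.11, 0.06 and 0.17 (adjusted p = 2.07e-06, 0.000708 and 2.78e-07), the proteasome and lysosome medians were both 0 (adjusted p = 0.126 and 0.0538), and that of the yolk sac -0.12 (adjusted p = 0.309). Killer cell genes then had a median of -2.67 (adjusted p = 0.0538). The yolk sac call ended without the low-count filter and with only the 2 groups in the fit (medians 0.06 and 0.08, adjusted p = 0.0797 and 0.0997). With the covariates the decidual call ended (median -0.37, adjusted p = 0.126). Without the 3 libraries lowest in yolk sac markers, which leaves trehalose 1 against lactotrehalose 1 and 2, the decidual, killer cell and proteasome calls ended (medians -0.21, -0.59 and 0.11, adjusted p = 0.942, 0.745 and 0.07). The yolk sac list then turned to higher with trehalose (median 0.93, adjusted p = 3.06e-10), but the libraries had been chosen by that list, so this is no test of it. Short transcripts were higher and long ones lower in this comparison as well, with medians of 0.11 and -0.16, and after the length correction the ribosomal and proteasome calls ended with medians of 0.02 and 0 (adjusted p = 0.616 and 0.987). The lysosome call also ended (adjusted p = 0.0539), but its median was 0.11 and had not shrunk.

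Of the ER stress genes, Pdia4, an ER disulfide isomerase, was at 450 ± 65.6 CPM with trehalose and 315 ± 31 CPM with lactotrehalose (log2 difference 0.51, 95% interval 0.08 to 0.95), and Manf, an ER stress-induced factor, at 268 ± 41.9 against 191 ± 27.2 CPM (0.49, interval 0.03 to 0.95). The prolactin-family gene Prl7a1 was at 115 ± 30.1 against 70 ± 12.9 CPM and Prl2c3 at 1290 ± 376 against 801 ± 203 CPM. Atp5g1 was at 72.2 ± 3.11 against 51.9 ± 12.2 CPM, and the lysosomal galactosidase gene Glb1 at 89.4 ± 5.49 against 68.4 ± 4.66 CPM. The cytotoxic granule genes Prf1 and Gzmb were at 2.36 ± 1.23 against 17.2 ± 20.2 CPM and at 1.22 ± 0.871 against 9.15 ± 10.7 CPM. Of the 10 killer cell genes, 7 passed adjusted over the list alone (smallest adjusted p = 0.0371), and 0 passed over all genes. In the decidual list Dcn, decorin, was at 522 ± 260 against 1360 ± 1020 CPM.

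The lists of autophagy, amyloid and preeclampsia genes did not pass between the disaccharides. Their medians were 0.03 (adjusted p = 0.537), -0.02 with the test pointing upward (adjusted p = 0.965) and -0.14 (adjusted p = 0.136). For single genes the intervals of the difference were -0.33 to 1.31 for Flt1 (log2 difference 0.49), -0.31 to 0.78 for Tfeb (0.23), -0.35 to 0.34 for Lamp1 (-0.01), -0.03 to 0.64 for Sqstm1 (0.30), -0.28 to 0.39 for Map1lc3b (0.05) and -2.55 to 2.91 for Ttr (0.18). Slc2a8, a glucose transporter reported to carry trehalose, had a log2 difference of 0.23 (interval -0.25 to 0.71). Treh, the enzyme that cleaves trehalose, had 0 to 16 counts per library and was too low to test. Of single genes, edgeR, DESeq2 and limma-voom each called 0, edgeR had 456 at an unadjusted p under 0.05, 209 higher and 247 lower, and 1041 genes (7.1%) did not overlap. Plekhg6 had the lowest p, at 17 ± 2.64 CPM with trehalose and 11 ± 0.606 CPM with lactotrehalose (log2 difference 0.62, interval 0.30 to 0.95, adjusted p = 0.999). Ldlrad4 was at 2.47 ± 0.35 against 4.62 ± 0.864 CPM and Anxa11 at 192 ± 19.2 against 137 ± 5.51 CPM.

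The disaccharide groups were also compared with NP serum, to ask whether they still differed from it. With edgeR 0 genes passed for either disaccharide, and limma-voom called 0. For trehalose, 987 genes had an unadjusted p under 0.05, 345 higher and 642 lower, 1630 (11.1%) did not overlap, and DESeq2 called 14, 4 higher and 10 lower. For lactotrehalose, 471 genes had an unadjusted p under 0.05, 39 higher and 432 lower, and 720 (4.91%) did not overlap. DESeq2 called 1 gene there, Plekhg6 (log2 fold change -0.98, adjusted p = 9.78e-06 with DESeq2 and 0.459 with edgeR).

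Whether the disaccharides moved genes opposite to PE serum was measured across 14669 genes, which are not independent replicates. The log2 fold changes of PE against NP serum correlated with those of trehalose against PE serum with r = -0.54, and with those of lactotrehalose against PE serum with r = -0.63. Both comparisons use the same PE serum libraries, which alone gives a negative value, and simulations without any effect gave r = -0.50 for each. Permutations of the group labels used differences of mean log2 CPM in place of fitted fold changes. Over 100 of them the mean r was -0.49 (SD 0.25) for trehalose and -0.48 (SD 0.27) for lactotrehalose. Of the 100, 68 and 55 were at or below the r of the real groups on that same measure. That r is not the fitted -0.54 or -0.63 and is not given here. Without lactotrehalose 3 the fitted r for lactotrehalose was -0.15. Without NP serum 1 the fitted r was -0.307 for trehalose and -0.421 for lactotrehalose. The planned version on genes changed by PE serum gave no value, since 0 genes passed.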

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

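The splits of gene counts, the correction for transcript length, the covariates, and the bound of 2 SE above 0 by which a median left by a correction was judged, in place of a share of 0.5 written earlier, were chosen only after the results they address were seen. The SE of a median was taken over the list's members as if they were independent. It leaves out the spread between libraries, so that bound does not show whether a median would hold in other samples.

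The 2 disaccharides share the PE serum background, dose and days, so a list past the test between them is a difference between groups under the same contrast. Lists past it were oxidative phosphorylation (adjusted p = 2.41e-08), junctional zone trophoblast (1.03e-07), ER stress (2.24e-06), ribosomal proteins (5.64e-05), proteasome (0.0078) and lysosome (0.0299), all higher with trehalose. Decidual stroma (0.00569), natural killer and T cells (0.00776) and the yolk sac (0.0387, with a median of 0.06, and scores of -1.89 with trehalose and -1.05 with lactotrehalose) passed as lower. With an estimated correlation 0 of the 9 passed (smallest adjusted p = 0.565). The killer cell genes were highest in lactotrehalose 3 (score 2.35), and without that library their adjusted p was 0.772.

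In the lists higher with trehalose, the length correction left the ER stress median at 0.29 in place of 0.29 (SE 0.04, adjusted p = 6.58e-07), the junctional zone median at 0.39 in place of 0.54 (SE 0.07, adjusted p = 2.37e-05) and the oxidative phosphorylation median at 0.12 in place of 0.23 (SE 0.03, adjusted p = 0.00615). Length as corrected for here thus did not account for the whole of these medians, and the part removed from the last 2 stays open to it. The correction took the ribosomal median from 0.18 (SE 0.03) to 0.02 (SE 0.02, adjusted p = 0.616) and the proteasome median from 0.11 (SE 0.03) to 0 (SE 0.03, adjusted p = 0.987), so both calls ended because the change itself went, and length stays a candidate explanation there (members of these and the oxidative phosphorylation list were 117 of the 12188 genes in the length fit). With the yolk sac and smooth muscle scores as covariates, which took the decidual median from -0.60 to -0.37 (adjusted p = 0.126), the medians were 0.55 for the junctional zone (SE 0.06, adjusted p = 2.19e-07), 0.27 for ER stress (SE 0.05, adjusted p = 2.38e-06), 0.25 for oxidative phosphorylation (SE 0.04, adjusted p = 3.47e-08), 0.21 for ribosomal proteins (SE 0.03, adjusted p = 8.7e-07) and 0.10 for the proteasome (SE 0.04, adjusted p = 0.0069). These 2 scores thus did not account for the whole of these medians. The junctional zone score was not a covariate, and the ER stress scores ran with it. In trehalose 1 to 3 ER stress was at 0.30, 0.28 and -0.19 and the junctional zone at 0.53, 0.55 and -0.29. In lactotrehalose 1 to 3 they were at 0.02, -0.05 and -0.41 and at 0.12, -0.09 and -0.61. The fit therefore does not separate these 2 lists. Without lactotrehalose 3 the ER stress median was 0.19 (SE 0.07, adjusted p = 0.0372) and the junctional zone median 0.28 (SE 0.05, adjusted p = 0.00966). That library alone thus did not account for the whole of these medians, while the part lost (shares kept 0.66 and 0.52) stays open to its tissue mix. A difference between the disaccharides stays open as well, untested beyond these lists, whose calls did not hold with an estimated correlation.

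Splits of the 6 libraries of a comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. For lists, the real count was 4 and the highest other 10 for PE against NP serum, where 10 of 10 splits were as large. The counts were 9 and 14 for trehalose against PE serum (7 splits as large), 7 and 15 for lactotrehalose against PE serum (8 splits), and 9 and 17 between the disaccharides (7 splits). The medians of the other splits were 7, 9, 13 and 10 in these 4 comparisons. In none of them did the real groups give more lists by camera than that median, so the number of lists past camera is no evidence of a group effect. For genes the real count was 0 in all 6 comparisons, which any split equals or exceeds (10 of 10 in each), so these counts say nothing about chance. The highest other count was 1 for PE against NP serum, 0 for either disaccharide against PE serum and for trehalose against NP serum, 83 between the disaccharides and 599 for lactotrehalose against NP serum. The split with 83 genes set trehalose 2, trehalose 3 and lactotrehalose 3, the libraries lowest in yolk sac markers, against the other 3. The split with 599 set NP serum 1, NP serum 3 and lactotrehalose 3, the highest of the 6 in smooth muscle markers, against the other 3. Both counts point to a structure of the samples that the groups do not follow.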

How the results depend on the processing

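Leaving out each library and changing the scaling, filter, tool, unit or block were planned, and 5 alternatives were chosen after seeing the data (2 sets of covariates, the length correction, and the fits without 3 or without 2 libraries).

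Gene counts stayed at 0 under every alternative except DESeq2, which called 26 genes for trehalose against PE serum, 1 for lactotrehalose against PE serum, 14 for trehalose against NP serum and 1 for lactotrehalose against NP serum. The cause was not tested. On simulated data DESeq2 made 49 false calls where edgeR made 3. Those data held changed genes and took their spread from edgeR, so they do not tell how many of the real DESeq2 calls are false. The number of lists past the threshold (4, 9, 7 and 9 in the 4 main comparisons, in the order PE against NP serum, trehalose, lactotrehalose, and trehalose against lactotrehalose) was 0, 0, 0 and 0 with an estimated correlation and 0, 0, 0 and 0 by fry. These tests allow for members that vary together, and fry compares no list with other genes. For lactotrehalose against PE serum it was 11 without the low-count filter, where more genes were tested, and 0 with the yolk sac and smooth muscle covariates, which cannot test those same lists. The cause of either was not tested further. With those covariates the other 3 counts were 4, 8 and 9, but not of the same lists. PE against NP serum went from 1 higher and 3 lower to 4 higher and 0 lower, trehalose against PE serum from 5 and 4 to 8 and 0, and the disaccharides from 6 and 3 to 8 and 1. The length correction gave 4, 6, 7 and 8 lists, of which 1 was higher and 5 were lower for trehalose against PE serum, and 3 and 5 between the disaccharides. The fit without the 3 libraries lowest in yolk sac markers gave 4, 8, 10 and 10. It had 6 higher and 2 lower for trehalose, 3 and 7 for lactotrehalose (4 and 3 in the main fit), and 9 and 1 between the disaccharides.

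Leaving out 1 library at a time gave 0 genes in every comparison. Lists ranged from 3 to 15 for PE against NP serum (15 without NP serum 1 and 10 without PE serum 1), 6 to 11 for trehalose, 6 to 11 for lactotrehalose (11 without lactotrehalose 1) and 7 to 13 between the disaccharides. The correlation of each disaccharide's change with that of PE serum ranged from -0.638 to -0.307 for trehalose and from -0.726 to -0.15 for lactotrehalose, with -0.307 without NP serum 1 and -0.15 without lactotrehalose 3. The cause was not tested. Of 6134 values of named genes under alternatives, 6010 had the sign of the main value and 124 the opposite sign, 13 had an adjusted p under 0.05, all with DESeq2, and 0 were both opposite and called. The alternatives reuse the same libraries and many of these genes were named for their low p, so a shared sign is not independent support.

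No label pairs the replicate numbers, and of 18 pairings of groups by number the correlations ran from -0.48 to 0.65, so the samples were not treated as paired. With the replicate block, 0 genes passed in each comparison and 4, 8, 8 and 9 lists did, without the chaperones for trehalose against PE serum (adjusted p = 0.057), and the correlations were -0.506 and -0.53. Depth was 15593035 counts or more per library. At the depth and spread of these libraries edgeR recovered 15% of simulated genes changed by 2-fold and 83% of those changed by 4-fold, and neither depth nor spread was varied to see which limits this.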

Other observations

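The tests on the yolk sac and smooth muscle lists, and the relation of Ttr to the yolk sac list, were chosen only after the results they address were seen.

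Lists that the report does not describe stayed short of the threshold. Interferon response genes were higher in 20 of 30 members with PE serum than with NP serum (median 0.09, adjusted p = 0.126), and antioxidant genes of the NRF2 pathway were lower in 19 of 28 (median -0.09, adjusted p = 0.147). With trehalose against PE serum, inflammation genes of the NF-kB pathway were lower in 19 of 28 members (median -0.15, adjusted p = 0.166) and glycogen trophoblast genes higher in 6 of 8 (median 0.23, adjusted p = 0.0782). Hypoxia response genes had medians of 0.07 with PE serum (adjusted p = 0.689), -0.07 with trehalose (0.327) and -0.10 with lactotrehalose (0.58). The list of sugar handling genes, which includes transporters and disaccharidases, had medians of -0.08 with trehalose (adjusted p = 0.852) and -0.12 with lactotrehalose (0.595).

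Yolk sac genes were lower as a list with either disaccharide by camera, calls that were lost with an estimated correlation (adjusted p = 0.756 and 0.835) and by fry (0.41 and 0.855), and trehalose 2, trehalose 3 and lactotrehalose 3 were far below the rest. The list was written beforehand, 23 of its 24 genes had a count in every library and 3 are in another list; over the 12 libraries its 21 members with at least 10 CPM moved together (median pairwise r = 0.94, within groups 0.91, without the 3 lowest libraries 0.88, highest of 200 random lists 0.26), so the amount of yolk sac in the collected tissue is a candidate explanation, with Afp at up to 26900 CPM and no sort or dissection step in the labels that would remove it. An effect of the disaccharides also stays open. The mean of the 6 disaccharide libraries lay below that of the 3 PE serum libraries (difference -2.9 log2 units, exact permutation p = 0.048, unadjusted, for 1 of 35 lists), although trehalose 1 lay within the PE serum range. The groups were pooled after both were seen to be low, so this p is no support for an effect. Taken singly against PE serum, the exact permutation p was 0.2 for trehalose and 0.1 for lactotrehalose. These data hold no measure of the tissue collected that would separate them.

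Smooth muscle and matrix genes were lower as lists with PE serum by camera, but both calls were lost with an estimated correlation (adjusted p = 0.876), no member passed, and the matrix call ended with the yolk sac and smooth muscle scores as covariates (median -0.27, adjusted p = 0.0735). The smooth muscle list's 10 members with at least 10 CPM moved together over the libraries (median pairwise r = 0.87, within groups 0.88, highest of 200 random lists 0.52), consistent with differing amounts of uterine muscle. Of the list's 14 genes, 13 had a count in every library and 1 is in another list. Vessel muscle of the placenta may also contribute to them, which was not tested. Actg2 was at 347 CPM in NP serum 3 and 110 CPM in NP serum 1, against 8.4 CPM in NP serum 2 and 9.14 to 49.5 CPM with PE serum. For an effect of PE serum the exact permutation p was 0.3, where 3 against 3 cannot give under 0.1, so it and the amount of muscle cannot be told apart.

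Ttr, a member of the yolk sac list, was related to the other 22 members over the 9 libraries outside the low group (Pearson r = 0.91, exact permutation p = 0.0013; Spearman rho = 0.87, exact permutation p = 0.0045). Without lactotrehalose 1 and NP serum 3, the 2 farthest libraries, r was 0.68. This was 1 relation, chosen after the values were seen, and no adjustment was made. The list's members with at least 10 CPM had a median pairwise r of 0.88 in the same 9 libraries. The relation thus restates for Ttr that members of this list moved together.

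NP serum 2 and PE serum 1, of different groups, were the most alike pair of libraries, with an SD of log2 differences of 0.145 over 5350 genes, against 0.233 for the closest pair within a group and a median of 0.552 between groups. The squared differences between their counts were 14.6 times those that counting error gives (chi-square per degree of freedom). Whether one of them was mixed up with another sample, such as one of the same litter, was not tested and the labels do not tell. A mix-up would change what the comparisons with PE or NP serum mean. Without both libraries 4, 6, 6 and 9 lists passed in the 4 main comparisons. The proteasome, junctional zone and erythroid calls for trehalose ended with medians of 0.06, 0.26 and 0.32 (adjusted p = 0.0845, 0.152 and 0.169). The labyrinth, smooth muscle and mesenchyme calls for lactotrehalose ended as well (adjusted p = 0.0978, 0.0799 and 0.0515), although the medians of 0.26, 1.28 and 0.70 were about as large as before, and so did the yolk sac call between the disaccharides (median 0.08, adjusted p = 0.0966). The first principal component held 41.9% of the variance and the groups accounted for 36.7% of it, where chance gives 27.3%. It correlated with the yolk sac score (r = 0.91) and the smooth muscle score (r = -0.65). Genes of the Y chromosome had list scores of 3.28 to 4.41 in 5 libraries (NP serum 1, NP serum 3, PE serum 2, trehalose 1 and lactotrehalose 1) and of -2.94 to -2.41 in the other 7. With that score as a covariate the lists past the threshold numbered 4, 9, 7 and 9.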
